A study of Oryza sativa with 8 samples.

How the data were processed

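The series holds 8 one-colour Agilent arrays of total leaf RNA from rice, 1 array per sample. Per the labels' protocols, RNA was amplified from an oligo dT primer with a T7 promoter, labelled with Cy3 and hybridised to a rice array with 8 fields per slide. Per the file headers, spots were read with Agilent Feature Extraction 10.7.3.1, all 8 arrays lay on 1 slide read in 1 scan, and probe positions refer to build IRGSP5. The deposited intensity values are the mean spot brightness, the median local background and the processed signal. Per the file headers the last is background-subtracted and detrended but not normalised between arrays. Flags mark outlier spots and signal well above background. The deposited series matrix holds log2 values whose scale no source stated. Each column equalled the log2 processed signal minus 1 constant per array, within 0.001 for at least 99.8% of 59803 probes. The constant was the 75th percentile, no gene was centred, and the column medians ran from -3.56 to -3.37. Neither the aligner of the probes nor the authors' statistical test is given in the sources used here.

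Samples were grouped by their titles as OsINO1 salt (n = 3), OsINO1 no salt (2 arrays) and PcINO1 salt (n = 3). The slide rows held OsINO1 salt replicates 1 and 2, the first no-salt array and PcINO1 salt replicate 2 in the upper row, and the other 4 arrays in the lower row. Median processed signals ran from 124 to 193 per array and median local background from 23.0 to 26.0.

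The groups, comparisons, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except the counting of the no-salt arrays. The plan had 1 limma fit on 8 samples. Over 267 probes spotted more than once, the 2 no-salt arrays turned out to differ by no more than the spots of 1 probe within an array, and their titles call them controls without calling them biological replicates, so their mean entered as 1 sample. This count of 1 was chosen after seeing the data, and the planned count of 2 samples was kept as an alternative under its own name. With 1 control sample the error of each test comes from the 6 salt arrays, and the control is assumed to vary as they do.

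Control spots and spots flagged as outliers were left out, and 70 probes then lacking a value on some array were not tested. The log2 processed signal minus the array's 75th percentile was used, and spots of one probe were averaged. A probe was tested if well above background on at least 2 arrays of at least 1 group, which left 46263 probes. A gene stood for its tested probe with the highest mean signal, and 9 of the 61 genes called between the lines had another tested probe of a different sequence. The 32358 tested genes comprised 29761 with a rice annotation project identifier and 2597 other transcripts named by the array design, among them 86 microRNA features. Gene descriptions are those of the array files and can be old.

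Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 33 lists with at least 5 tested genes, with an estimated correlation and with fry beside it. With the estimated correlation 0 lists passed in any comparison, and fry called 0, 0 and 1. The estimate was 0.63 for light-reaction and for ribosomal genes, 0.55 for chlorophyll synthesis, 0.48 for LEA, 0.46 for classic salt and 0.20 for carbon-fixation genes. These lie far above the preset, so the p-values of these lists at the preset can be far too small. For heat shock genes it was 0.003, below the preset, so a higher correlation does not account for the loss of that call. Lists were matched by words in the gene descriptions. Calls adjusted over a list alone were not corrected for the number of lists. Between the lines under salt such calls also arose in many lists that did not pass. Examples are senescence, with 2 genes higher and 3 lower, auxin, with 1 higher and 4 lower, and transposons, with 1 higher. Such a call is therefore not evidence particular to its list. The 28 lists that did not pass in the first comparison had medians from -0.31 to 0.81, the 29 in the second from -0.50 to 0.40 and the 29 in the third from -0.27 to 1.01. For a gene not well above background on every array of a group, only a bound is given: the brighter group's mean over the dimmer group's mean of the lowest signal above background or the probe's own signal, whichever was higher. This bound holds for the processed signal only: with normexp background and its added offset of 50, the fold of each such gene named was smaller than its bound.

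Named genes were, for each comparison, the 8 largest called rises and falls of at least 1 on the log2 scale with arrays apart between groups and a described function, or else the 3 with the smallest p in that direction, together with up to 4 members of each described list by smallest p, the classic salt genes and the INO1 genes. Genes outside this rule are named as chosen after their values were seen. In the main limma fit each p-value sets a difference against the spread between salt arrays of one group. The spread between unsalted plants does not enter it.

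The fit was tested on simulated arrays with each gene's mean and estimated spread, where 200 of 32358 genes were changed in each comparison. There was 1 run per comparison. Noise was drawn independently for each gene and alike for every array. The real arrays departed from this, with genes that moved together and array weights from 0.35 to 1.62. The shares that follow hold for the simulated setting and do not measure detection in these data. Between the lines under salt, 12% of genes changed 2-fold, 86% of those changed 4-fold and 98% of those changed 8-fold were called. For salt against no salt in the OsINO1 line the shares were 0%, 36% and 66%, and for the PcINO1 line under salt against no salt 0%, 22% and 76%. Unchanged genes made up 7.7%, 7% and 7.1% of the simulated calls for salt against no salt in the OsINO1 line, between the lines under salt, and for the PcINO1 line under salt against no salt. Alternatives comprised other backgrounds, scalings, probe filters, probe summaries, variance models, array weights, blocks for replicate number and slide row, thresholds, the deposited log2 values and the omission of each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.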

Results

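Gene expression was measured in leaves of 2 rice lines, one introgressed with OsINO1 and the other with PcINO1. INO1 genes encode L-myo-inositol-1-phosphate synthase, which catalyses the first step of inositol synthesis. OsINO1 is the rice gene, and PcINO1 is the name in use for the gene of Porteresia coarctata, a wild rice relative that grows in saline habitats. Plants were kept in 150 mM NaCl for 5 days or left without salt. The 8 one-colour arrays comprised 3 of the OsINO1 line under salt, 2 of the OsINO1 line without salt and 3 of the PcINO1 line under salt. No unsalted PcINO1 array was among them, so the line difference without salt was not measured. Each array carried 61657 spots of 59805 probes, and between 69.2% and 79.7% of the probes were well above background, with no saturated spot. The same mark was carried by 31.7% to 53.3% of the random-sequence control spots and 18.8% to 29.6% of the genomic control spots of an array, so it does not by itself show a transcript. After removal of dim probes 32358 genes were tested. The labels call the later salt-treated sets biological replicates and do not say whether plants were pooled. The number of arrays limits the precision of every value.

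The 2 arrays without salt were the most alike of all pairs. Their SD per spot was 0.09 on the log2 scale over 267 probes spotted more than once. Spots of one probe within each of these arrays had SDs of 0.07 and 0.11, while pairs of salt arrays of one group had SDs per spot of 0.27 to 0.45. An SD per spot is the SD of the difference divided by the square root of 2. Over 27114 genes well above background on every array, the difference between the no-salt arrays had an SD of 0.27. For pairs of salt arrays of one group it was 0.50 to 0.69. These last values are SDs of the difference itself and are not on the scale of the SDs per spot. Genes dim on any array were left out of these values. Over the 267 probes the no-salt arrays thus differed by no more than the spot noise, which was not measured for dimmer probes, and they were counted as 1 sample. The spread between plants without salt was treated as not measured, and the salt arrays supplied the error of each test. Counting them as 2 samples, as had been planned, called more genes in each comparison, and those counts are given beside the main ones.

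The rice INO1 gene Os03g0192700 was among the brighter genes on every array. Its normalised log2 signal, relative to the 75th percentile of each array, was 4.76 ± 0.29 (SD, n = 3) in the OsINO1 line under salt, 4.13 without salt (n = 1) and 4.24 ± 0.17 (SD, n = 3) in the PcINO1 line under salt. The single OsINO1 salt arrays read 4.47, 5.06 and 4.76, and the PcINO1 salt arrays read 4.42, 4.08 and 4.23. None of the differences passed the limma test over all genes. Salt against no salt in the OsINO1 line gave 0.63 (SE 0.30, adjusted p = 0.867) and the PcINO1 line against the OsINO1 line under salt gave -0.52 (SE 0.21, adjusted p = 0.298). In the latter the 3 PcINO1 arrays lay below the 3 OsINO1 salt arrays, the nearest of them at 4.42 and 4.47. The unadjusted p was 0.0441 (limma). Its list held 1 tested gene, so adjustment over the list alone leaves this p unchanged and adds no support. The PcINO1 line under salt against no salt gave 0.11 (SE 0.30, adjusted p = 0.98). The sign of the last value turned with quantile normalization and with the mean of the gene's probes. The probe used lies on chromosome 3, positions 4824745 to 4824804 of build IRGSP5, and is annotated to the coding sequence and the 3' untranslated region. The other 2 probes of the gene share positions 4824695 to 4824754. Whether any of them binds the PcINO1 transcript, or tells an introgressed copy from the resident one, is not known here. A second INO1 gene, Os10g0369900, was well above background on 1 of 8 arrays for each of its probes and was not tested.

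The first comparison asked how leaves of the OsINO1 line responded to salt. The 23 genes of late embryogenesis abundant (LEA) proteins and dehydrins, which protect cells during water loss, rose as a group, with a median log2 difference of 3.14 over no salt (1.86 with normexp background). Of the 23, 19 had higher values under salt (camera, adjusted p = 1.25e-07; adjusted p = 0.525 with an estimated correlation). The level differed between the 3 salt arrays, whose list medians were 1.42, 4.22 and 4.12 above no salt in replicates 1, 2 and 3. Dehydrin RAB 16D (Os11g0453900) had a log2 difference of 6.07 (SE 2.26) and dehydrin RAB 16C (Os11g0454000) one of 4.59 (SE 1.5). The LEA group 1 gene Os06g0110200 lay 2.86 (SE 0.83) and the LEA 3 family gene Os01g0314800 1.39 (SE 0.33) above no salt. No member of this list passed the test on its own, over all genes or adjusted over the list alone.

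A list of 10 classic salt- and drought-responsive genes also rose in the OsINO1 line, by a median of 1.04, with 9 of the 10 higher (adjusted p = 0.00362; adjusted p = 0.529 with an estimated correlation). Array medians were 0.69, 1.51 and 1.16 in replicates 1, 2 and 3, and without replicate 2 the adjusted p was 0.0559. SalT (Os01g0348900), a mannose-binding lectin induced by salt, stood 3.93 above no salt (SE 2.04), and the vacuolar Na+/H+ antiporter gene Os07g0666900 stood 1.23 above it (SE 0.58). DREB2A (Os01g0165000), a regulator of dehydration-responsive genes, differed by 1.26 (SE 0.61) and the proline-synthesis gene Os05g0455500 by 0.84 (SE 0.40). None of the 10 was called alone, over all genes or adjusted over the list alone. Among ion transporters the sodium transporter gene HKT1;1 (Os04g0607500) had a log2 difference of 2.63 (SE 0.71, adjusted p = 0.617).

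Smaller group shifts accompanied these in the OsINO1 line. The 103 cell-division genes, among them histones and cyclins, rose by a median of 0.15, with 61 higher and 42 lower (adjusted p = 0.00362; adjusted p = 0.465 with an estimated correlation), and 1 member was called higher when adjusted over the list alone. Histone H4 (Os03g0119900) was 2.87 above no salt (SE 0.34) and histone H2A (Os03g0279200) 1.70 (SE 0.34). Histone H3 (Os11g0155900), not well above background without salt, was at least 5.10-fold higher (1.83-fold with normexp background). The 151 cytosolic ribosomal protein genes fell by a median of 0.16, with 118 of them lower (adjusted p = 0.00435; adjusted p = 0.937 with an estimated correlation). Among them were 40S protein S9 (Os03g0379500) at -0.81 (SE 0.30) and 60S protein P0 (Os11g0135400) at -0.72 (SE 0.28). This call was lost without OsINO1 salt replicate 1 (adjusted p = 0.0581) or 2 (median -0.07, adjusted p = 0.157) and with array weights (adjusted p = 0.058). The 150 heat shock genes rose by a median of 0.06, with 93 higher and 57 lower (adjusted p = 0.0415; adjusted p = 0.465 with an estimated correlation). That call was lost without OsINO1 salt replicate 2 (adjusted p = 0.227), OsINO1 salt replicate 3 (median 0.13, adjusted p = 0.165) or the first no-salt array (median 0.10, adjusted p = 0.101). It was also lost with quantile normalization (adjusted p = 0.101), with no filter on dim probes (adjusted p = 0.138) and with only probes above background on all 8 arrays (adjusted p = 0.0743), while scaling by array medians gave a median of 0.10. The small heat shock protein Oshsp17.3 (Os03g0266900) had a log2 difference of 2.89 (SE 1.14) and mitochondrial HSP70 (Os03g0113700) one of 1.14 (SE 0.41). No member of the ribosomal or heat shock list was called, over all genes or adjusted over the list alone. In all 5 lists passed in this comparison, and 12 did without OsINO1 salt replicate 1 and 2 without OsINO1 salt replicate 2.

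Gene by gene, limma called 0 of 32358 genes between salt and no salt in the OsINO1 line, with a smallest adjusted p of 0.225, and called 1 without OsINO1 salt replicate 3. At an unadjusted p under 0.05 there were 1960 genes, 881 higher and 1079 lower. The described genes nearest to the threshold, each at adjusted p = 0.225, were higher for a xyloglucan fucosyltransferase (Os04g0449200, 2.48, SE 0.25), histone H4 and a receptor-like kinase (Os12g0638100, 2.12, SE 0.26). They were lower for a Barwin-domain gene (Os11g0592100, -4.61, SE 0.52), vacuolar sorting receptor 7 (Os04g0611400, -3.05, SE 0.36) and a RING/PHD zinc finger gene (Os02g0738200), which was not well above background on the salt arrays and at least 8.26-fold lower there (2.62-fold with normexp background). The fucosyltransferase gene Os04g0449200 stood at 1.88 without the second no-salt array and at 3.08 without the first. WRKY transcription factor 29 (Os07g0111400) stood at -1.83 (SE 0.27), abscisic stress ripening protein 1 (Os01g0959200) at -2.73 (SE 0.45) and an acidic class III chitinase (Os01g0660200) at -4.21 (SE 0.99), none past the threshold over all genes. Adjusted over the list alone, 2 WRKY genes (smallest adjusted p = 0.0194) and 1 abscisic acid gene (adjusted p = 0.0105) were called lower. With the 2 no-salt arrays counted as 2 samples, limma called 101 genes, 27 higher and 74 lower. With the row of the array on the slide as a block, the same 8-sample fit called 48 in place of 101, 13 higher and 35 lower. Under this block the medians were 3.51 for LEA, 1.08 for classic salt, 0.15 for cell-division, -0.16 for ribosomal and 0.05 for heat shock genes. Within the upper slide row, 2 salt arrays against 1, these medians were 2.61, 1.11, 0.17, -0.18 and 0.12. Within the lower row, 1 array against 1, they were 4.15, 1.15, 0.12, -0.07 and 0.10.

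The second comparison asked how the PcINO1 line differed from the OsINO1 line when both were under salt. On average, genes of photosynthetic carbon fixation, chlorophyll synthesis and the light reactions were higher in the PcINO1 line, and LEA and dehydrin genes were lower. OsINO1 salt replicates 2 and 3 had the highest LEA medians and the lowest medians of the other lists. PcINO1 salt replicate 1 lay above no salt for all of these lists. Whether the lists followed the line or the strength of the salt response on single arrays was not tested. All 23 carbon-fixation genes had higher means in the PcINO1 line, with a median log2 difference of 0.65 (camera, adjusted p = 9.64e-05; adjusted p = 0.718 with an estimated correlation). So had all 15 chlorophyll-synthesis genes, with a median of 0.68 (adjusted p = 4.65e-04; adjusted p = 0.752 with an estimated correlation). Of 54 light-reaction genes 50 were higher, with a median of 0.38 (adjusted p = 8.08e-04; adjusted p = 0.831 with an estimated correlation). Of 23 LEA and dehydrin genes 17 were lower, with a median of -2.24 (adjusted p = 0.00103; adjusted p = 0.831 with an estimated correlation).

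The carbon-fixation list included RuBisCO activase (Os04g0658300), which had a difference of 0.93 (SE 0.26). It also held the alpha and beta subunits of the RuBisCO-binding chaperonin (Os12g0277500, 1.75, SE 0.32, and Os06g0114000, 1.17, SE 0.21), which assist protein folding in the chloroplast and fix no carbon themselves. Of this list 0 members were called over all genes and 2 were called higher when adjusted over the list alone. In chlorophyll synthesis, protoporphyrinogen oxidase (Os01g0286600) differed by 1.37 (SE 0.31), the Mg-chelatase subunit gene Os03g0811100 by 1.23 (SE 0.29) and coproporphyrinogen oxidase (Os04g0610800) by 1.11 (SE 0.30). Of these genes 0 were called over all genes and 5 were called higher when adjusted over the list alone, without correction for the number of lists. Among the light-reaction genes, the photosystem II assembly factor HCF136 (Os06g0729650) was at 1.35 (SE 0.28) and an antenna protein (Os09g0439500) at 1.42 (SE 0.50), whereas a photosystem II 10 kDa protein (Os07g0147550) was at -1.88 (SE 0.39). Of this list 0 members were called over all genes or adjusted over the list alone. The carbon-fixation medians relative to no salt were 0.45, 0.51 and 0.39 on PcINO1 salt replicates 1, 2 and 3, and 0.13, -0.60 and -0.40 on OsINO1 salt replicates 1, 2 and 3. Light-reaction medians were 0.31, 0.31 and 0.40 against 0.48, -0.38 and -0.37, so OsINO1 salt replicate 1 lay above the PcINO1 arrays for this list. Chlorophyll-synthesis medians were 0.38, 0.64 and 0.10 against 0.20, -0.39 and -0.31, so the arrays of both lines overlapped there too. Without OsINO1 salt replicate 1 the medians were 1.06 for carbon fixation and 0.65 for the light reactions, and the members of the 3 lists named here, except the antenna and 10 kDa proteins, were called over all genes (adjusted p from 0.0382 to 0.0437). Without OsINO1 salt replicate 2 that of chlorophyll synthesis was 0.44, and without OsINO1 salt replicate 3 the light reactions had a median of 0.21 and did not pass (adjusted p = 0.0533). With quantile normalization their median was 0.16.

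**Figure D1:**
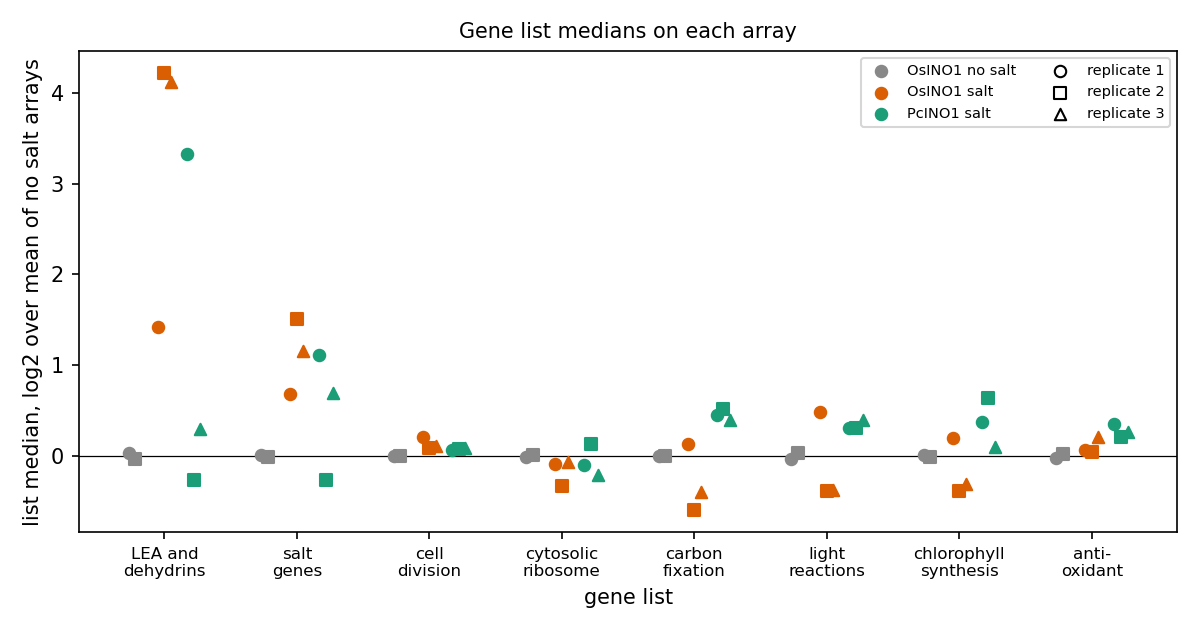
Median log2 signal of the genes of 8 lists on each of the 8 arrays (vertical axis, log2 relative to the mean of the 2 no-salt arrays; horizontal axis, gene list), with colours for groups and symbols for replicates. The LEA and dehydrin medians spread from 1.42 to 4.22 over the OsINO1 salt arrays and from -0.26 to 3.32 over the PcINO1 salt arrays, while the carbon-fixation medians of the PcINO1 salt arrays lie between 0.39 and 0.51.

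The LEA and dehydrin medians were 3.32, -0.26 and 0.29 above no salt on PcINO1 salt replicates 1, 2 and 3, so 1 PcINO1 array lay above OsINO1 salt replicate 1 and the other 2 lay near the unsalted level. The list median between the lines was -3.62 without PcINO1 salt replicate 1, -0.97 without PcINO1 salt replicate 2 and -3.48 without OsINO1 salt replicate 1, and the list passed in each case. It was -1.44 with only probes above background on all 8 arrays. The LEA group 1 gene Os06g0110200 was at -3.13 (SE 0.59), without overlap between the arrays of both lines. It was the 1 member called lower when adjusted over the list alone, with 0 called over all genes. Dehydrin RAB 16C (Os11g0454000) was at -3.31 (SE 1.06) and SalT (Os01g0348900) at -2.98 (SE 1.44; -1.97 without PcINO1 salt replicate 2), both with overlapping arrays. The 10 classic salt genes had a median of -0.50 and did not pass (adjusted p = 0.101), but did without OsINO1 salt replicate 1 (adjusted p = 0.0331), without PcINO1 salt replicate 1 (adjusted p = 0.00741), with normexp background and with the slide row as a block. Of these 10 genes 0 members were called, over all genes or adjusted over the list alone. DREB2A (Os01g0165000) stood at -1.26 (SE 0.43) and HKT1;1 (Os04g0607500) at -1.74 (SE 0.50), neither past the threshold. Without OsINO1 salt replicate 1 the LEA gene Os06g0110200 (adjusted p = 0.0479) and HKT1;1 (adjusted p = 0.0372) were called over all genes.

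At single genes, limma called 61 of 32358 between the PcINO1 and OsINO1 lines under salt, 42 higher and 19 lower. Carbonyl reductase 1 (Os02g0640800, chromosome 2, 26592425 to 26592484), an NADPH-dependent reductase of carbonyl compounds, was 94.4-fold higher in the PcINO1 line (log2 6.56, SE 0.38, adjusted p = 0.00302), at 2.51 ± 0.38 (SD, n = 3) against -4.05 ± 0.69 (SD, n = 3). A Myb-domain transcription factor (Os07g0137000), a transcript annotated as malic enzyme (TC491466), a RING/PHD zinc finger gene (Os02g0738200) and a protein kinase gene (Os11g0667700) were not well above background on the OsINO1 salt arrays. In the PcINO1 line they were at least 16.3-fold, 7.50-fold, 4.95-fold and 4.79-fold higher. With normexp background the folds were smaller than these bounds, at 5.31, 3.33, 2.06 and 2.01, and the zinc finger and kinase genes were not called (adjusted p = 0.0941 and 0.106). A WRKY45-like transcription factor (Os05g0322900), in rice known for its part in disease resistance, rose by 2.43 (SE 0.24, adjusted p = 0.0296), and vacuolar sorting receptor 7 (Os04g0611400) by 2.40 (SE 0.25, adjusted p = 0.0359). The gene similar to Stable protein 1 (Os01g0516600) was called at 2.53 (SE 0.25, adjusted p = 0.0296) with its brightest probe, but its other 2 probes gave a median of -0.21, and with the mean of its probes it stood at 1.13 and was not called (adjusted p = 0.14). Each of these genes but carbonyl reductase 1 lost its call in at least 3 of the 5 fits without OsINO1 salt replicate 2 or 3 or without PcINO1 salt replicate 1, 2 or 3, with an adjusted p of up to 0.166 (Os04g0611400 without PcINO1 salt replicate 3).

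Lower in the PcINO1 line were a jasmonate-induced protein gene (Os10g0132300), which fell by 5.02 (SE 0.45, adjusted p = 0.0244) from 1.73 ± 0.57 to -3.29 ± 0.77 (SD, n = 3 each), and the nearby NBS-LRR disease resistance gene Os10g0131800, which fell by 2.22 (SE 0.21, adjusted p = 0.0261). An alpha-xylosidase gene (Os01g0130400), whose enzyme class trims cell-wall xyloglucan, fell by 3.11 (SE 0.28, adjusted p = 0.0221), a pectinesterase inhibitor gene (Os06g0711800) by 2.83 (SE 0.32, adjusted p = 0.046; 1.67 with normexp background) and a beta-glucanase gene (Os05g0375400) by 1.73 (SE 0.18, adjusted p = 0.0358). The cytochrome P450 gene CYP71K14 (Os06g0497350) and an auxin-induced gene (Os09g0547100) were not well above background on the PcINO1 arrays and were at least 2.32-fold and 1.87-fold lower there. With normexp background they were 1.47-fold and 1.43-fold lower and were not called (adjusted p = 0.16 and 0.199). Each of these genes lost its call in at least 3 of the same 5 fits, with an adjusted p of up to 0.196 (Os06g0711800 without OsINO1 salt replicate 3). Of 71 WRKY genes 1 was called over all genes and 6 were called higher when adjusted over the list alone, and the list itself did not pass (adjusted p = 0.243). Os07g0680400 stood at 2.27 (SE 0.30; called without OsINO1 salt replicate 1, adjusted p = 0.0434) and WRKY69 (Os08g0386200) at 2.84 (SE 0.52). Some of the called genes had no described function and were chosen after their values were seen. Os05g0270500 and Os11g0303800 were at least 379-fold and 155-fold higher in the PcINO1 line, Os12g0550600 was 7.59 and Os01g0725000 6.36 higher on the log2 scale, and Os05g0266900 was at least 10.3-fold lower. With normexp background the 5 genes were still called, with smaller differences: 92.5-fold, 34.2-fold, log2 5.63, log2 4.62 and 3.39-fold.

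**Figure D2:**
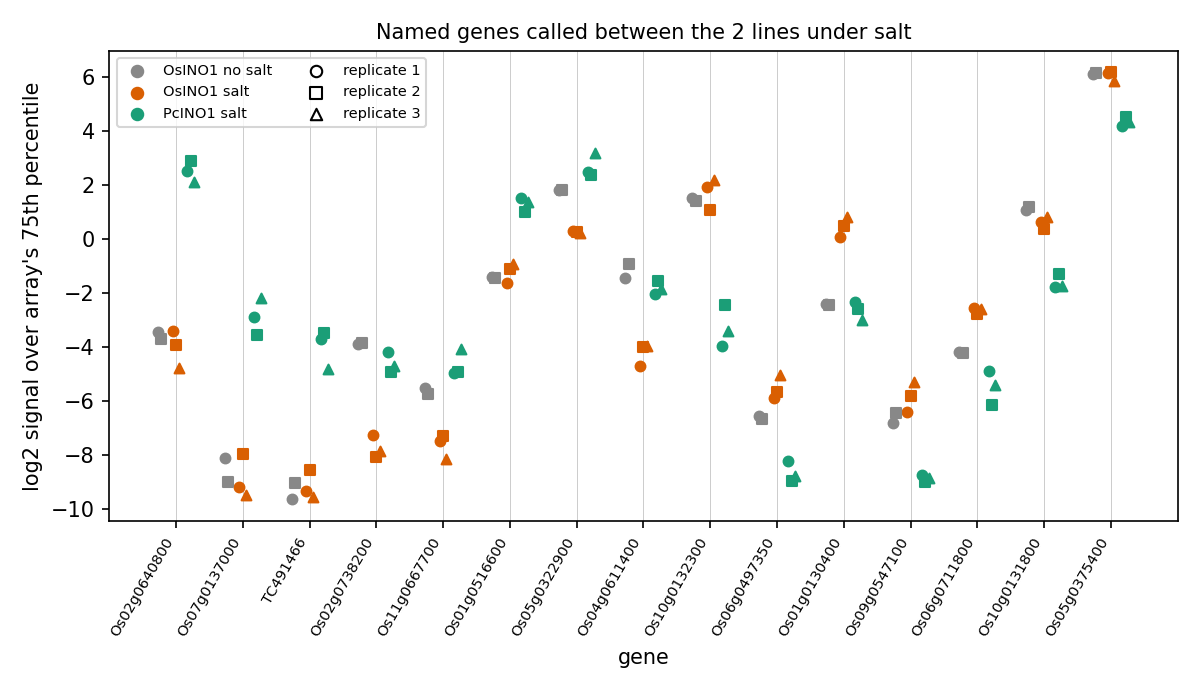
Normalised log2 signal (vertical axis, relative to the 75th percentile of each array) of the named genes called between the lines under salt (horizontal axis) on each of the 8 arrays, with colours for groups and symbols for replicates. The rule for named genes required the 3 PcINO1 salt arrays to lie apart from the 3 OsINO1 salt arrays, so this separation is set by the choice of genes. Carbonyl reductase 1 (Os02g0640800) had means of 2.51 on the PcINO1 and -4.05 on the OsINO1 salt arrays.

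The smallest adjusted p of this comparison was 0.000842, and 5221 genes had an unadjusted p under 0.05 (limma), 3138 higher and 2083 lower. At 7176 genes (22.2%) the 2 sets of 3 arrays did not overlap, where chance gives 10% for a single gene. Genes moved together across arrays, so by chance the share in 1 split can lie far from 10%. No share for other splits is given here, so the excess does not by itself show a line difference. The count depended on single arrays. Without OsINO1 salt replicate 1 limma called 1444 genes, 1068 higher and 376 lower, with all 61 among them, and 10 lists passed in place of 4, as 7 did without PcINO1 salt replicate 1. The count was 34 without OsINO1 salt replicate 2, 24 without PcINO1 salt replicate 2, and 21 without OsINO1 salt replicate 3, PcINO1 salt replicate 1 or PcINO1 salt replicate 3. With the no-salt arrays counted as 2 samples 246 genes were called, 146 higher and 100 lower, 60 of the 61 among them. With the slide row as a block, a fit of the 6 salt arrays called 22 in place of 61, 17 higher and 5 lower and all among the 61, and 8 lists passed in place of 4. The medians with the block were 0.80 for carbon fixation, 0.68 for chlorophyll synthesis, 0.47 for the light reactions and -3.0 for LEA genes. Within the upper slide row, 1 PcINO1 array against 2, these medians were 0.61, 0.82, 0.16 and -3.56. Within the lower row, 2 against 1, they were 0.85, 0.51, 0.74 and -1.88. Carbonyl reductase 1 (Os02g0640800) passed in 22 of 22 alternatives, and each other described gene named here lost its call in some of them, with an adjusted p of up to 0.206.

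In the last comparison the PcINO1 line under salt was set against the OsINO1 line without salt, so line and salt differed together. Light-reaction genes rose by a median of 0.34 (adjusted p = 0.00749), carbon-fixation genes by 0.50 (adjusted p = 0.00889), antioxidant genes by 0.33 and chlorophyll-synthesis genes by 0.31 (both adjusted p = 0.0328), each with adjusted p = 0.941 with an estimated correlation. Higher values were found for 50 of 54 light-reaction, 20 of 23 carbon-fixation, 34 of 45 antioxidant and 15 of 15 chlorophyll-synthesis genes, of which 0 were called singly, over all genes or adjusted over the list alone. Antioxidant members included a glutathione peroxidase (Os04g0683850) at 0.96 (SE 0.24; 0.60 without the second no-salt array) and a peroxisomal ascorbate peroxidase (Os04g0223300) at 1.22 (SE 0.34), whereas catalase A (Os02g0115700) was at -1.44 (SE 0.52). Sedoheptulose-bisphosphatase (Os04g0234600) of the carbon-fixation list was at 0.69 (SE 0.38), HCF136 (Os06g0729650) at 1.22 (SE 0.40) and the Mg-chelatase subunit gene Os03g0811100 at 0.81 (SE 0.41). LEA and dehydrin genes had a median of 1.01 and did not pass (adjusted p = 0.145), but did without PcINO1 salt replicate 2 (adjusted p = 0.00891) or 3 (adjusted p = 0.0189). Nor did the classic salt genes pass, with a median of 0.54 (adjusted p = 0.477; 0.0291 without PcINO1 salt replicate 2) and 0 of 10 called, over all genes or adjusted over the list alone. Without the first no-salt array 0 lists passed. Chlorophyll synthesis was also lost without PcINO1 salt replicate 2 (median 0.16, adjusted p = 0.382) or OsINO1 salt replicate 3 (adjusted p = 0.0529) and had a median of 0.47 without PcINO1 salt replicate 3. The antioxidant call was also lost without PcINO1 salt replicate 1 (adjusted p = 0.253), PcINO1 salt replicate 2 (adjusted p = 0.0753) or OsINO1 salt replicate 3 (adjusted p = 0.0529). Among other settings it was lost with normexp background (adjusted p = 0.0707), quantile normalization (adjusted p = 0.095), no filter on dim probes (adjusted p = 0.0979) and the replicate block (adjusted p = 0.0509). Chlorophyll synthesis was lost with quantile normalization (adjusted p = 0.0513) and no filter on dim probes (adjusted p = 0.0554), and the light reactions with quantile normalization (median 0.16, adjusted p = 0.0513).

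The 41 genes of inositol metabolism had a median difference of 0.08 in this comparison. They did not differ from other genes (camera, adjusted p = 0.69), whereas fry, which asks only whether the list's own genes moved one way on balance, gave an adjusted p of 0.0307. The member with the smallest p was a sugar and inositol transporter gene (Os12g0512100), 1.34 higher (SE 0.24) and the 1 gene called when adjusted over the list alone, with 0 called over all genes. Between the lines under salt the same gene was at 0.84 (SE 0.17) and an inositol monophosphatase gene (Os07g0558200) at 1.32 (SE 0.25; called over all genes without OsINO1 salt replicate 1, adjusted p = 0.0404), where 2 of the 41 were called higher when adjusted over the list alone and fry gave an adjusted p of 0.0833.

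Limma called 12 genes between the PcINO1 line under salt and the unsalted OsINO1 line, 11 higher and 1 lower, and 1812 genes had an unadjusted p under 0.05, 883 higher and 929 lower. Quantile normalization gave 16 higher and 7 lower, and normexp background correction 17 higher and 13 lower. Carbonyl reductase 1 (Os02g0640800) rose by 6.09 (SE 0.54, adjusted p = 0.0409), a call lost without any one salt array but OsINO1 salt replicate 3, with an adjusted p of up to 0.192 (without PcINO1 salt replicate 1), and without the second no-salt array (adjusted p = 0.0556). The uncharacterised genes Os12g0550600, Os11g0303800, Os05g0270500 and Os01g0725000 were also called higher and Os05g0266900 lower. Os05g0266900 was not called with normexp background (adjusted p = 0.242). All of them but Os12g0550600 lost their calls without PcINO1 salt replicate 1 or 2, with an adjusted p of up to 0.159 (Os05g0270500 without PcINO1 salt replicate 1). Without OsINO1 salt replicate 1 Os11g0303800 and Os01g0725000 lost theirs too (adjusted p = 0.0533 each), and Os05g0270500 lost its call in 7 of the 8 omissions, all but that of the first no-salt array. Described genes next to the threshold were an NB-ARC resistance gene (Os11g0684100) at 2.09 (SE 0.21, adjusted p = 0.0663) and the malic enzyme transcript TC491466, at least 8.52-fold higher (adjusted p = 0.0899; 3.24-fold with normexp background). On the lower side were the NBS-LRR gene Os10g0131800 at -2.74 (SE 0.30, adjusted p = 0.0826), a kinase gene (Os09g0569800) at -2.27 (SE 0.28, adjusted p = 0.123) and an AP2-domain transcript that was at least 6.96-fold lower (adjusted p = 0.115; 0.0387 without OsINO1 salt replicate 3; 2.42-fold with normexp background), while 1 AP2/ERF gene was called lower when adjusted over the list alone. The smallest adjusted p was 0.00243. One gene was called without PcINO1 salt replicate 1 or 2, 7 without PcINO1 salt replicate 3, 8 without OsINO1 salt replicate 1 and 21 without the first no-salt array. With the no-salt arrays as 2 samples 194 genes were called, 92 higher and 102 lower. With the slide row as a block, the same 8-sample fit called 88 in place of 194, 44 higher and 44 lower. Under the block the medians were 0.39 for light reactions, 0.51 for carbon fixation, 0.31 for antioxidant and 0.34 for chlorophyll-synthesis genes. Within the upper row, 1 array against 1, these were 0.31, 0.56, 0.26 and 0.65. Within the lower row, 2 against 1, they were 0.33, 0.41, 0.32 and 0.17.

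Both comparisons against the unsalted arrays shared that control, and 0 genes were called in both with the same direction, since limma called 0 in one of them. With the no-salt arrays as 2 samples 35 genes were shared, 10 higher and 25 lower, where 100 simulations of unchanged groups against the same 2 controls shared 0 and independent lists would share 0.08 and 0.23. The first value leaves out the effects and the second the shared controls, so the excess over either does not measure a shared effect. Across genes, which are not independent replicates, the fold changes of both comparisons correlated at 0.46. In 100 simulations of unchanged groups with a shared control the correlation was 0.75. The covariance was 0.17, against a simulated 0.18. The simulated correlation is set by the number of arrays per group, since the control was drawn with the spread of the salt arrays. Neither value set beside the simulation therefore measures a shared effect. A split of the 2 controls would leave 1 array for each comparison and was not made, so part of any overlap may come from them.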

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

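The alternatives were planned. The main count of the no-salt arrays as 1 sample was chosen after seeing the data, and the planned count of 2 samples stands here as an alternative. Numbers are genes called for OsINO1 salt against no salt, PcINO1 against OsINO1 under salt, and PcINO1 salt against no salt, from main counts of 0, 61 and 12. Normexp background gave 7, 96 and 30, an adjusted p under 0.1 gave 0, 141 and 24, array weights 0, 143 and 22, and the 2 no-salt arrays as 2 samples 101, 246 and 194. Quantile normalization gave 23 and trend with robust variances 19 for the third comparison. No filter on dim probes gave 32 and only probes above background on all 8 arrays 30 for the second, with 1 for the third, as did a fit of only the 2 groups compared (for the second it changes nothing, since 1 control sample adds no error). The slide row as a block gave 48, 22 and 88, in place of 101, 61 and 194 on the same arrays without it, which are all 8 for the comparisons with no salt and the 6 salt arrays between the lines. Leave-one-out counts ran from 0 to 1, from 21 to 1444 and from 1 to 21, and a group left with 1 sample was assumed to vary like the others. Overlap of the comparisons against the control was 0, and 4 with normexp, 12 with the row block, 35 with 2 control samples, and 0 to 1 leaving out arrays. The cause of these moves was not tested, apart from the fewer or more samples and genes that the settings themselves set.

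Lists past the threshold, 5, 4 and 4, became 0, 0 and 0 with an estimated correlation. They were 10 with normexp, 8 with the slide row block and 9 with array weights for the second comparison, 8 with array weights for the first, and 2 with quantile normalization or no dim filter for the third. Leaving out arrays gave 2 to 12, 4 to 10 and 0 to 5. The INO1 gene Os03g0192700 in the third comparison was -0.032 with quantile normalization and -0.002 with the mean of probes, against 0.11. Leaving out arrays it ranged from 0.48 to 0.78, -0.66 to -0.37 and 0.02 to 0.20. Of the 430 alternative values of 20 named genes called between the lines, 329 stayed past the threshold, and 98 of 128 for 6 genes in the third comparison, with 0 reversed. With normexp background each named gene given as a bound fell short of that bound.

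Deviations of same-numbered arrays of the 2 lines under salt correlated at -0.45, -0.20 and -0.06 across genes, and those of arrays of unlike number at -0.19 to 0.33. No pairing by replicate number was thus seen. With so few arrays per line and genes that moved together, these values cannot show whether the sets were grown or processed together. On the arrays used for the row block the replicate block gave 0 calls in place of 101 in the first comparison, 20 in place of 61 in the second and 33 in place of 194 in the third. Signal over background limits what can be measured: 69.2% to 79.7% of the probes on an array were well above it.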

Other observations

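All tests of explanations in this part were chosen after the result was seen.

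Beyond those in the report no list passed camera in the chosen fit, and several passed in alternatives. The 145 cell-wall genes had a median of 0.08 under salt in the OsINO1 line (camera, adjusted p = 0.0589; 0.0497 with quantile normalization and 0.0109 without OsINO1 salt replicate 1; 1 called higher when adjusted over the list alone, 0 over all genes). The 5 phloem and vascular genes had a median of 0.81 under salt in the OsINO1 line (camera, adjusted p = 0.0656; 0.047 with normexp background and 0.0177 without OsINO1 salt replicate 1; 2 called higher and 1 lower when adjusted over the list alone, 0 over all genes), with a sucrose transporter (Os03g0170900) at 1.40 (SE 0.32), and a median of -0.50 between the lines under salt (adjusted p = 0.0596, but 0.0235 with normexp background, 0.0481 with the slide row block, 0.0315 without OsINO1 salt replicate 1 and 0.029 without PcINO1 salt replicate 3; 2 called lower when adjusted over the list alone). Array medians over no salt were 0.29, 1.24 and 0.90 in OsINO1 salt replicates 1, 2 and 3 and 0.16, -0.05 and -0.31 in PcINO1 salt replicates 1, 2 and 3. The 8 proline genes were all lower in the PcINO1 line under salt, with a median of -0.28 that did not pass (adjusted p = 0.0596), but did with normexp background (adjusted p = 0.041), with the slide row block and without OsINO1 salt replicate 1 (adjusted p = 0.0214) or PcINO1 salt replicate 1 (adjusted p = 0.0327). Of 14 photorespiration genes 12 were higher, with a median of 0.40 (adjusted p = 0.0596), a list that passed with normexp background (adjusted p = 0.041) and without OsINO1 salt replicate 1 (adjusted p = 0.0214) or 2 (adjusted p = 0.0469). The sugar-phosphate gene Os08g0409100, a trehalose-6-phosphate phosphatase, was at 1.77 (SE 0.49) and an alkaline alpha-galactosidase (Os08g0495800) at -1.72 (SE 0.33), neither past the threshold over all genes except without OsINO1 salt replicate 1 (adjusted p = 0.0404 and 0.0487). Adjusted over the list alone, 2 trehalose genes were called higher and 2 lower, and 1 gene of galactinol and raffinose metabolism higher and 1 lower.

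Of the 10 splits of the 6 salt arrays into 2 groups of 3, the real split called 61 genes and the highest of the others called 15, so 1 split reached the real count, and 10 splits are too few for a share under 0.05. The split with 15 calls set OsINO1 salt replicate 1 and PcINO1 salt replicates 2 and 3 against the rest, and the split by slide row called 0.

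OsINO1 salt replicate 1 stood apart from its group, with a LEA and dehydrin median of 1.42 against 4.22 and 4.12, and so did PcINO1 salt replicate 1, with 3.32 against -0.26 and 0.29. PcINO1-line RNA in place of the named RNA on OsINO1 salt replicate 1 is argued against by 49 genes that separated the lines by at least 2 log2 units on the other 7 arrays: at 81.6% of them this array lay nearer to the OsINO1 arrays, with a median position of 0.10 on a scale from 0 for OsINO1 to 1 for PcINO1, where PcINO1 salt replicates 1, 2 and 3 lay at 0.95, 0.83 and 0.98. The measure is coarse: PcINO1 salt replicate 1 lay nearer to its own line at 89.6% of 48 such genes and PcINO1 salt replicate 2 at 70.8% of 65, the lowest share of the 8 arrays. Scaling is argued against too, since the gap in its LEA median to the lower of the other 2 arrays was at least 2.70 under each of 4 scalings. A weaker or later salt response of the plants of OsINO1 salt replicate 1 may account for its level. So may a partial admixture of other RNA, and neither was tested. The treatment label of no salt array was tested either, including PcINO1 salt replicates 2 and 3, whose LEA medians lay near the unsalted level. The median SD of the LEA genes was 1.37 over the OsINO1 and 2.21 over the PcINO1 salt arrays, against 0.33 and 0.22 over all genes.

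The large differences between the lines at single genes may come from sequence differences under single probes. A sequence difference under 1 probe only is argued against for 6 called genes whose second probe, of another sequence, showed over 0.5 of the difference, among them carbonyl reductase 1 (Os02g0640800) at a ratio of 0.90, the WRKY45-like gene (Os05g0322900) at 1.03 and the NB-ARC gene (Os11g0684100) at 1.06. Whether the probes of a gene overlap was not checked, so a sequence difference that reaches both probes stays open for these 6 genes. For the other 55 called genes the explanation stays open in full, and 3 of them had a second probe under 0.25 of the difference, including Os01g0516600 at -0.08. A candidate explanation in the genome, that called genes share chromosome segments in which the lines differ, stays open: 12 of 50 called genes with a position had a called neighbour within 500 kb, against a median of 7 and a 95th percentile of 13 in 10000 random gene sets (permutation p = 0.12). Os10g0131800 and Os10g0132300 were one such pair, and a difference in genetic background between the lines, apart from INO1, was not tested by the design.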
